A study of Mus musculus with 9 samples.

How the data were processed

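The data were expression values of 9 Affymetrix arrays of biotin-labelled cRNA, 3 each for Shh, Ihh and Vehicle. Per the labels' protocols, small intestinal mesenchyme was taken from C57Bl/6J E18.5 embryos, freed of epithelium, cultured for 48 h, treated for 24 h and pooled from 6 wells per treatment into 3 samples, and 6 ug of total RNA was labelled. The deposited values were log2 expression per probe set, 1 value for each of 45101 probe sets on each array. Per the submitters' processing notes GCOS and RMA (robust multi-array average, which corrects background, normalizes between arrays and summarises probes on the log2 scale) were used, with versions not given in the sources used here. That the values are log2 was read from their range, about 2.78 to 14.20, and no further filter by the authors is recorded. Values between arrays are therefore relative to a common distribution, so a shift of all genes together would not be seen, and low levels are compressed towards the background. No batch, scan date or slide was given in the sources used here.

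Probe sets were named through the platform annotation, in which 34945 had 1 gene symbol, 932 had several and 9160 had none. A further 64 were control probe sets. Symbols were checked through Entrez identifiers against a RefSeq gene table of GRCm38.p6, which was used for names only. It held 34741 of the identifiers and changed 0 symbols. A gene was measured by its single-symbol probe set with the highest mean over the 9 arrays, which gave 18193 genes, of which 9010 had several probe sets. For the named genes past the threshold in the main comparison, every other probe set of the gene moved in the same direction.

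Group means were fitted to all 9 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, so that the comparisons shared 1 estimate of the spread (6 residual degrees of freedom, 3.88 prior). The 4 comparisons were both ligands against Vehicle, Shh against Vehicle, Ihh against Vehicle and Shh against Ihh. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes within a comparison, with a threshold of 0.05. All adjusted p of single genes are from limma. Groups, comparisons, the tests of these comparisons, the 26 gene lists, the rule for named genes and all alternatives but 4 were chosen before the data were examined. Some tests of explanations in the closing section, and its lists of resident macrophage and MHC class II genes, were chosen later.

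The 26 lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with a correlation estimated per list and with fry. They were hedgehog target genes, hedgehog pathway components, BMP and TGF-beta signalling, WNT signalling, smooth muscle contractile genes, inflammatory cytokines and chemokines, NF-kB target genes, interferon-stimulated genes, immune-restraining genes, complement genes, extracellular matrix, matrix proteases and inhibitors, cell cycle, cholesterol synthesis, hypoxia and glycolysis, stress and immediate early genes, mesenchymal growth factors and fibroblast markers, and markers of epithelium, endothelium, immune cells, enteric neurons and glia, interstitial cells of Cajal, mesothelium, red blood cells and adipocytes. Single members were counted over all genes tested and again with p adjusted over the list alone.

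Named genes were the 10 largest rises and 10 largest falls past the threshold for both ligands whose treated and Vehicle arrays did not overlap, and the 5 of each for the other comparisons. Named in every comparison were Gli1, Ptch1, Hhip, Foxf1, Foxf2, Foxl1, Bmp4, Myocd, Acta2, Myh11, Il6, Ccl2, Cxcl1 and Cxcl10. Up to 4 members per list with the smallest p in the main comparison were added, or any called between the ligands. Csf1r, Laptm5, Cdh1, Krt8, Epcam, Xist and Eif2s3y fell outside this rule and were chosen after their values were seen.

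The steps were tested on simulated data in which known genes were changed in 18193 genes with the spread of these arrays, over 10 runs. For both ligands against Vehicle, limma recovered 47% of genes changed 1.25-fold, 88% at 1.5-fold and 97.4% at 2-fold, with 4.65% false calls. For Shh against Vehicle recovery was 36.2%, 82.4% and 95.2% with 5.43% false calls, and for Ihh against Vehicle 33.2%, 82.4% and 96% with 4.89%. Camera called 2 unchanged lists in 20 runs of 26 lists. Genes were drawn independently of each other in these simulations. They therefore cannot show how camera behaves on lists of correlated genes, and recovery and false calls may differ in the real data.

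The counts of called genes and the named genes were recomputed with the replicate number as a block, with another quantile normalization, with arrays centred on their medians, without dim genes (under the 40th percentile of level), with the mean of a gene's probe sets, with every probe set tested singly, without less specific probe sets, with a trended and robust variance model, with array weights, with only the groups compared, with at least 1.5-fold, with a threshold of 0.01 and without each array in turn. The 2 thresholds were not applied to single named genes. Lists were recomputed with the block, the other normalization, centred arrays, without dim genes, with the mean of probe sets and without each array, and the agreement of the ligands with centred arrays, without dim genes and without each array. After the data had been seen, 4 alternatives were added, the epithelium marker mean, the first residual component or the Xist level as a covariate, and the fit without the 2 arrays highest in epithelium markers. The agreement of the ligands was set beside 100 simulations of unchanged groups, in which the Vehicle arrays were simulated too and shared by both comparisons.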

Results

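Gene expression was measured in mesenchyme of the small intestine from E18.5 mouse embryos (late gestation), after the epithelium had been taken off. Mesenchyme is the connective tissue and muscle precursor compartment under the gut epithelium. Transcripts of immune cells were also present, such as Csf1r at 12.00 to 12.35 log2. Which cells a change arose in was not tested. The cells were cultured for 48 h and then treated for 24 h with Sonic hedgehog (Shh), Indian hedgehog (Ihh) or Vehicle, 3 arrays for each. Shh and Ihh are secreted ligands that the gut epithelium makes and the mesenchyme receives. The 6 wells of each treatment had been pooled at random into 3 samples, so the replicates were pools of wells and the p-values measured the spread between pools. By the sex-linked transcripts Xist and Eif2s3y, given at the end, the pools also differed in the sex of their embryos, unevenly over the treatments. The question of the study was which genes of the mesenchyme respond to hedgehog signalling. Array medians lay between 5.87 and 5.92 log2, and pairs of arrays correlated with Pearson's r between 0.991 and 0.998 across probe sets, which are not independent replicates. Low values are compressed towards background, so changes of genes that reached below these medians on any array may be understated and do not rank the genes. The medians served as a working mark and are not a measured background. The words at least mark this compression below and give no bound on the spread between arrays. The change of Hhip, for example, was as small as 0.49 log2 without 1 array. Among the genes named below as changed, those that reached below the medians were Hhip, Gli1, Cd28, Kynu, Angptl1, Il6, Il1b, Cxcl2, Fpr2, Serpinb2, Stfa3, Acod1, Ifit1, Clec4e, Cfb and Dpt. The difference between the 3' and 5' probe sets of Gapdh, a sign of RNA quality, was -0.08 to 0.03 log2 on the Vehicle arrays, -0.19 to -0.15 on 5 treated arrays and -0.04 on Ihh 1, and that of actin was 0.28 on Vehicle 1 and 0.12 to 0.19 on the others. No depth applies to arrays, and their number limited the precision. Ligand dose and the make-up of the vehicle are not given in the sources used here.

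Both hedgehog ligands together were compared with Vehicle as the main comparison (6 arrays against 3). Of the hedgehog target genes 3 of 20 rose, and of the inflammatory cytokines and chemokines 13 of 35 fell. Ptch1, the hedgehog receptor whose own transcription the pathway drives, rose from 9.14 ± 0.10 log2 with Vehicle to 10.55 ± 0.29 with Shh and 10.68 ± 0.26 with Ihh (SD, n = 3 each), 2.78-fold for both ligands together. Fpr2, a formyl peptide receptor of phagocytes, was at least 12.5-fold lower, and Il6, an inflammatory cytokine, was at least 3.33-fold lower with the ligands. Of 18193 genes tested, limma placed 274 past the threshold, of which 79 rose and 195 fell, with 7 rises and 43 falls of at least 2-fold.

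Among the hedgehog target genes, 20 were measured, 3 rose and 0 fell over all genes tested, and 7 rose and 0 fell when adjusted over the list alone. Ptch1 changed by 1.48 ± 0.14 log2 (SE, adjusted p = 0.000622). Hhip, a membrane protein that binds and restrains hedgehog ligands, changed by at least 0.58 ± 0.10 (adjusted p = 0.0243). Gli1, a transcription factor induced by the pathway, changed by at least 0.89 ± 0.18 (adjusted p = 0.0443). Of the forkhead factors of gut mesenchyme, Foxf1 differed by 0.22 ± 0.05 (adjusted p = 0.0736), Foxf2 by 0.13 (adjusted p = 0.547) and Foxl1 by 0.25 (adjusted p = 0.213), all short of the threshold. Bmp4, a secreted growth factor of the villus core, differed by 0.21 (adjusted p = 0.375). As a group the targets lay above other genes (camera adjusted p = 3.86e-05, and adjusted p = 0.0386 with an estimated correlation). The call of Gli1 held without Shh 2 or Shh 3 but ended without any of the other 7 arrays, at an adjusted p of up to 0.155. The call of Hhip ended without Shh 2, Shh 3, Vehicle 1 or Vehicle 2, at up to 0.119.

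Of the 20 hedgehog pathway components, 0 rose and 1 fell, and 3 rose and 2 fell when adjusted over the list alone. The gene that fell was Gas1, a cell surface co-receptor for hedgehog ligands, at -0.68 ± 0.10 log2 (adjusted p = 0.011). Gli2, the main activating transcription factor of the pathway, differed by 0.33 (adjusted p = 0.0677). The list did not stand apart from other genes (camera adjusted p = 0.231, and adjusted p = 0.54 with an estimated correlation). Without Vehicle 1 or Vehicle 2 the call of Gas1 ended, at up to 0.0661.

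Genes of the smooth muscle programme were higher in part. Myocd, the coactivator that drives smooth muscle differentiation, rose 2.28-fold (1.19 ± 0.20 log2, adjusted p = 0.0224). Synpo2, an actin-binding protein of muscle, rose by 0.87 ± 0.12 (adjusted p = 0.00676) and Itga8, an integrin of smooth muscle and mesenchyme, by 0.47 ± 0.09 (adjusted p = 0.0443). Of the 21 smooth muscle contractile genes 3 rose and 0 fell, and 4 rose and 1 fell when adjusted over the list alone. The fall was that of Smtn, at 8.25 to 8.60 log2 on the treated arrays against 8.73 to 8.81 with Vehicle. The structural genes Acta2 and Myh11 differed by 0.15 (adjusted p = 0.482) and 0.27 (adjusted p = 0.571), neither past the threshold. The list lay above other genes with the preset correlation (camera adjusted p = 9.94e-05) and lost its call at an adjusted p = 0.465 with an estimated correlation. In the list means per array Ihh 1 (-0.02) lay below Vehicle 2 (0.07) and Vehicle 3 (0.04). The call of Myocd ended without Shh 1, Vehicle 1 or Vehicle 2, at up to 0.104, and that of Itga8 without any array but Shh 3, at up to 0.198.

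Inflammatory cytokines and chemokines fell as a group. Of 35 measured, 0 rose and 13 fell, and 0 rose and 18 fell when adjusted over the list alone. The acute-phase gene Saa3 fell by 2.52 ± 0.17 log2 (SE, adjusted p = 6.32e-05), and the changes of the neutrophil chemokine Cxcl2 and the cytokine Il1b were -2.03 ± 0.22 (adjusted p = 0.00172) and -1.73 ± 0.13 (adjusted p = 0.00012). Il6 fell by 1.74 ± 0.19 (adjusted p = 0.00172), and the changes of Cxcl1 and the monocyte chemokine Ccl2 were -1.50 ± 0.14 (adjusted p = 0.000745) and -1.10 ± 0.15 (adjusted p = 0.00554). Cxcl10, an interferon-induced chemokine, fell by 0.71 ± 0.12 (adjusted p = 0.0225), a call that ended without Shh 1, Shh 3, Vehicle 1 or Vehicle 2, at up to 0.12. The list lay below other genes (camera adjusted p = 1.93e-13, and adjusted p = 0.0115 with an estimated correlation). On each array of both ligands its mean relative to the Vehicle mean lay between -0.67 and -0.47 log2, as the plot of list means per array shows, with -0.63 on Ihh 1, where the Gapdh difference lay within the range of Vehicle.

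NF-kB target genes, which this inflammatory transcription factor switches on, also fell. Of 19 measured, 0 rose and 6 fell, and 0 rose and 13 fell when adjusted over the list alone. Sod2, a mitochondrial superoxide dismutase, fell by 0.98 ± 0.06 log2 (adjusted p = 4.58e-05). The changes of the bacterial lipoprotein receptor Tlr2, the nuclear cofactor Nfkbiz and the kinase gene Ikbke were -1.11 ± 0.07, -0.84 ± 0.08 and -0.75 ± 0.09 (adjusted p = 6.32e-05, 0.000868 and 0.00286). The list lay below other genes (camera adjusted p = 7.96e-13), a call lost at an adjusted p = 0.0589 with an estimated correlation.

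**Figure D1:**
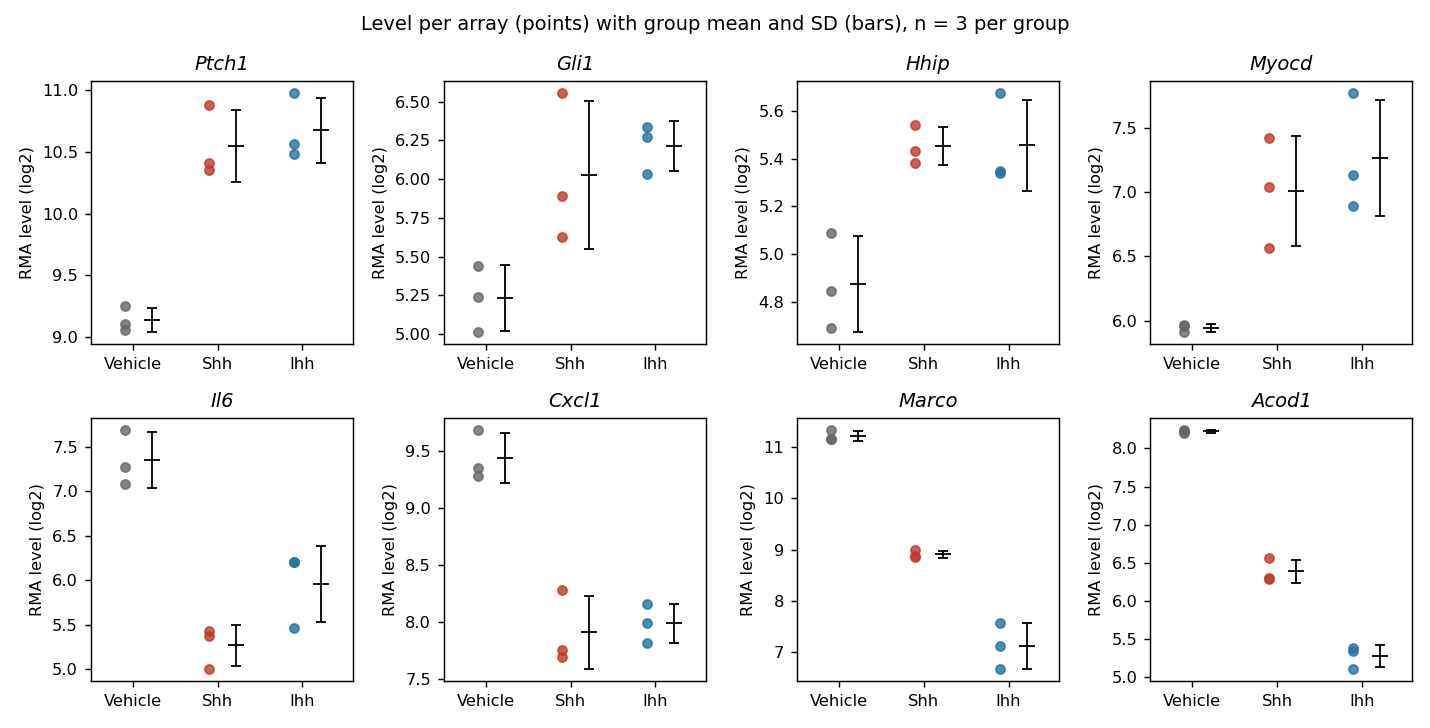
Expression in log2 of Ptch1, Gli1, Hhip, Myocd, Il6, Cxcl1, Marco and Acod1 on each array, by treatment, with points for arrays and the group mean and SD. In each of the 8 panels the 6 arrays treated with a ligand lie on one side of the 3 Vehicle arrays.

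Serpinb2 lay at 4.15 to 4.75 log2 and Stfa3 at 3.79 to 4.18 on the treated arrays, near the red blood cell gene Slc4a1 at 4.30 to 4.55 on all arrays. Levels of different probe sets are not directly comparable, so this nearness does not show that Serpinb2 or Stfa3 lay at background. The interferon-stimulated gene Ifit1 was at least 4.85-fold lower. Serpinb2, an inhibitor of plasminogen activators, was at least 11.3-fold lower, Marco, a macrophage scavenger receptor, 9.17-fold lower, and Arg1, which breaks down arginine, 5.91-fold lower. Fpr2 and Serpinb2 both had an adjusted p of 5.62e-06, Marco 5.93e-06 and Arg1 3.09e-05. Stfa3, a cathepsin inhibitor of myeloid cells, was at least 5.42-fold lower, Acod1, which makes itaconate in activated macrophages, at least 5.23-fold lower, Cxcl3, a neutrophil chemokine, 4.98-fold lower and Clec4e, a receptor for microbial glycolipids, at least 4.53-fold lower, with adjusted p of 0.00102, 8e-07, 0.000622 and 0.000492. The 6 treated arrays lay below all 3 Vehicle arrays in each of these genes but Slc4a1. Beside Ptch1 and Myocd, genes that rose were Ltc4s, which makes leukotriene C4 (2.45-fold, adjusted p = 1.87e-05), Hsd11b1, which regenerates active glucocorticoid (2.27-fold, adjusted p = 0.00325), Cd28, a co-stimulatory receptor of T cells (at least 2.27-fold, from 4.10 to 4.29 log2 on the Vehicle arrays, adjusted p = 0.0201), and Kynu, an enzyme of tryptophan breakdown (at least 2.26-fold, adjusted p = 0.000492). H2-Aa, a chain of the MHC class II molecule, rose 2.09-fold (adjusted p = 0.0112), Angptl1, a secreted angiopoietin-like protein, at least 1.87-fold (adjusted p = 0.0119), and Cx3cr1, the fractalkine receptor of macrophages, 1.83-fold (adjusted p = 0.0384). The calls of Cd28 and Angptl1 ended without Vehicle 1 or Vehicle 2, at up to 0.102 and 0.0741, and that of Cx3cr1 ended without Ihh 2, Ihh 3, Shh 2, Shh 3, Vehicle 1 or Vehicle 3, at up to 0.167.

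Immune cell markers moved apart. Of 19 measured, 1 rose and 6 fell, and 1 rose and 7 fell when adjusted over the list alone. Cd14, a co-receptor for endotoxin, fell by 1.66 ± 0.10 log2 (adjusted p = 3.09e-05), and the changes of the macrophage surface receptor Adgre1, the integrin chain Itgam and the oxidase subunit Cybb were -1.04 ± 0.08, -0.91 ± 0.09 and -0.90 ± 0.06 (adjusted p = 0.000269, 0.00107 and 7.41e-05). Laptm5, a lysosomal protein of blood cells, rose by 0.37 ± 0.07 (adjusted p = 0.0347). The macrophage growth factor receptor Csf1r differed by 0.00 (adjusted p = 0.995), at 12.00 to 12.35 log2 on the 9 arrays. The list lay below other genes (camera adjusted p = 0.00108), a call lost at an adjusted p = 0.267 with an estimated correlation.

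Interferon-stimulated genes were lower with the ligands and also differed between the Vehicle arrays. Of 19 measured, 0 rose and 3 fell, and 0 rose and 18 fell when adjusted over the list alone. Ifit1, an antiviral protein that binds foreign RNA, fell by 2.28 ± 0.46 log2 (adjusted p = 0.0435), and the changes of Usp18, which restrains interferon signalling, and Rsad2, an antiviral enzyme, were -1.98 ± 0.40 (adjusted p = 0.0447) and -1.65 ± 0.29 (adjusted p = 0.0259). For Usp18, 5 of the 6 treated arrays lay below all Vehicle arrays. The antiviral membrane protein Bst2 differed by -1.11 (adjusted p = 0.0513). The list lay below other genes (camera adjusted p = 3.93e-16), a call lost at an adjusted p = 0.25 with an estimated correlation of 0.907. Around the Vehicle mean, the list's mean was 0.41 log2 on Vehicle 1, 0.41 on Vehicle 2 and -0.82 on Vehicle 3, against -0.69 to -1.38 on the 6 treated arrays. The calls of Ifit1 and Usp18 each ended without any array but Vehicle 3, at up to 0.193 and 0.199, and that of Rsad2 without Ihh 3, Shh 1, Shh 2, Vehicle 1 or Vehicle 2, at up to 0.135.

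**Figure D2:**
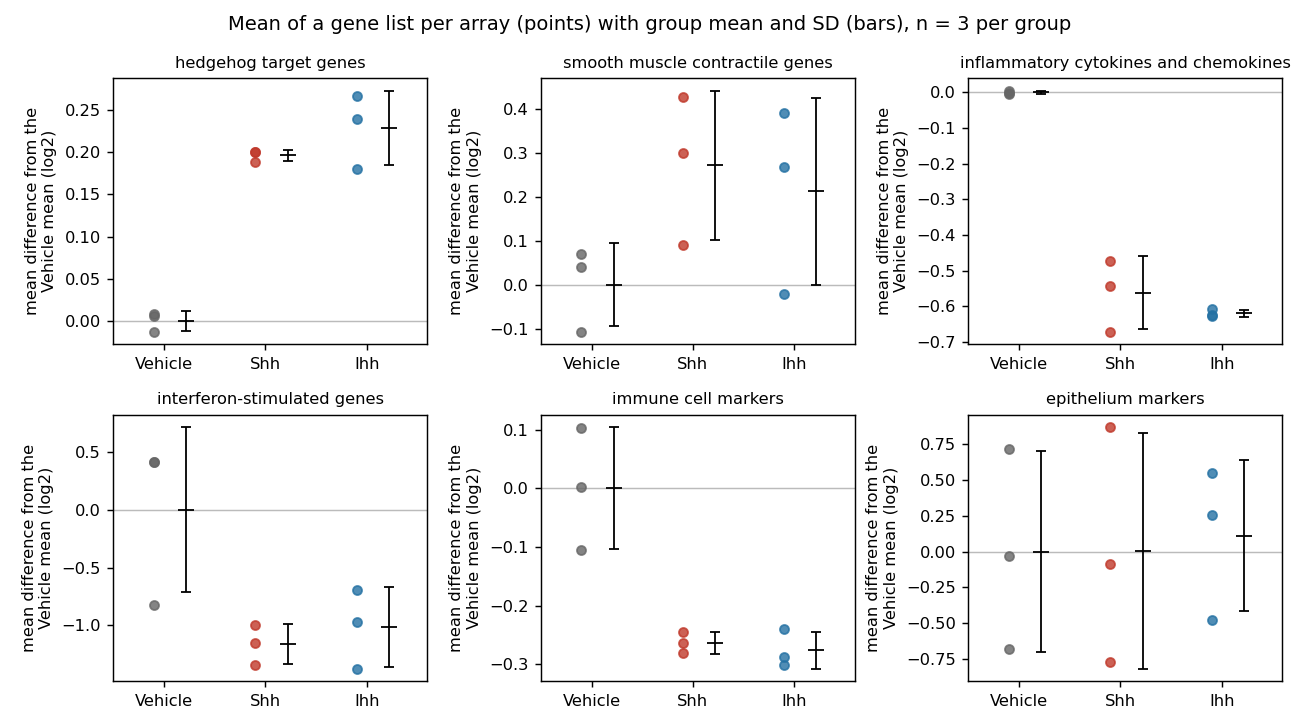
Mean log2 level of the measured genes of the hedgehog target, smooth muscle, inflammatory, interferon, immune cell and epithelium lists on each array, relative to the Vehicle mean. The inflammatory list lies at -0.47 or lower on all 6 treated arrays, the interferon list lies at -0.82 on Vehicle 3, and the epithelium list spans -0.77 to 0.87 with no order by treatment.

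Several lists of the tissue environment lay below other genes with the preset correlation and lost that call with an estimated one. Of 15 matrix proteases and inhibitors 0 rose and 3 fell, and 0 rose and 7 fell when adjusted over the list alone (camera adjusted p = 2.56e-06, and adjusted p = 0.142 with an estimated correlation). They were Mmp9, a gelatinase, at -0.98 ± 0.12 log2 (adjusted p = 0.00344), the metalloprotease inhibitor Timp1 at -0.40 ± 0.06 (adjusted p = 0.015) and the aggrecanase Adamts4 at -0.37 ± 0.07 (adjusted p = 0.0364). Of 30 extracellular matrix genes limma called 0 (3 higher and 7 lower at an unadjusted p under 0.05), with 2 rises and 7 falls when adjusted over the list alone, and fibronectin, Fn1, differed by -0.28 (adjusted p = 0.0507). The camera adjusted p was 0.0295, and the adjusted p = 0.54 with an estimated correlation. Of 16 hypoxia and glycolysis genes limma called 0 (0 higher and 10 lower unadjusted), with 8 falls when adjusted over the list alone (camera adjusted p = 7.45e-08, and adjusted p = 0.225 with an estimated correlation), and Pfkl, a glycolytic enzyme, differed by -0.40 (adjusted p = 0.0589). Of 16 immune-restraining genes limma called 0 (0 higher and 4 lower unadjusted), with 1 fall when adjusted over the list alone (camera adjusted p = 0.00793, and adjusted p = 0.225 with an estimated correlation), and Socs3, which damps cytokine signalling, differed by -0.48 (adjusted p = 0.0589). Of 16 endothelium markers limma called 0 (0 higher and 9 lower unadjusted), with 7 falls when adjusted over the list alone (camera adjusted p = 4.14e-07, and adjusted p = 0.267 with an estimated correlation). Of 16 enteric neuron and glia markers limma called 0 (1 higher and 4 lower unadjusted), with 1 rise and 1 fall when adjusted over the list alone (camera adjusted p = 0.0445, and adjusted p = 0.541 with an estimated correlation). The 27 cell cycle genes went the other way and lay above other genes (camera adjusted p = 0.00136, and adjusted p = 0.541 with an estimated correlation), with 26 above 0, 0 called by limma (2 higher and 0 lower unadjusted) and 0 when adjusted over the list alone. In the list means per array, treated and Vehicle arrays were apart for matrix proteases (-0.39 to -0.16 against -0.05 to 0.04) and immune-restraining genes (-0.26 to -0.10 against -0.05 to 0.05). The groups overlapped in the other lists of this part. For cell cycle Ihh 1 was the lowest of all arrays (-0.17) and Vehicle 3 (0.07) lay above Shh 3 (0.05). For hypoxia and endothelium Vehicle 3 (-0.19 and -0.16) lay below Ihh 1 (-0.03 and 0.04). The call of Timp1 ended without Vehicle 2, at 0.0663, and that of Adamts4 without any array but Ihh 1 or Ihh 3, at up to 0.171.

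Signalling and fibroblast lists held single changes and did not stand apart from other genes. Of 31 BMP and TGF-beta signalling genes 0 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.446, and adjusted p = 0.541 with an estimated correlation). It was the BMP antagonist Grem1, at -0.33 ± 0.06 log2 (adjusted p = 0.0303). Of 27 WNT signalling genes 1 rose and 1 fell, and 2 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.542, and adjusted p = 0.541 with an estimated correlation). They were the secreted modulator Dkk3 at 0.41 ± 0.07 (adjusted p = 0.0296) and the ligand Wnt5a at -0.42 ± 0.08 (adjusted p = 0.0279). Of 21 mesenchymal growth factors 1 rose and 1 fell, and 1 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.1, and adjusted p = 0.257 with an estimated correlation). Igf1 rose by 0.77 ± 0.10 (adjusted p = 0.00406) and Fgf7, a growth factor for epithelium, fell by 0.71 ± 0.14 (adjusted p = 0.0443). Of 11 fibroblast markers 1 rose and 1 fell, and 1 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.304, and adjusted p = 0.495 with an estimated correlation), the transcription factor Tcf21 at 0.47 (adjusted p = 0.0197) and the matrix protein Dpt at -0.68 (adjusted p = 0.0346). Apart from Igf1, which held without any 1 array, these calls ended when single arrays were left out. For Grem1 these were any Ihh or Vehicle array (adjusted p up to 0.152), and for Dkk3 any but Ihh 1 or Shh 3 (up to 0.141). For Wnt5a they were any but Ihh 1, Shh 3 or Vehicle 3 (up to 0.0684), for Fgf7 any but Shh 1 or Shh 2 (up to 0.126), for Tcf21 Shh 2 or Vehicle 1 (up to 0.104), and for Dpt any but Ihh 1, Ihh 3 or Vehicle 3 (up to 0.155).

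Of 16 stress and immediate early genes 0 rose and 3 fell, and 0 rose and 4 fell when adjusted over the list alone. They were transcription factors induced early after stimulation, Fos at -0.53 ± 0.07 log2 (adjusted p = 0.00406), Egr1 at -0.52 ± 0.09 (adjusted p = 0.0296) and Junb at -0.43 ± 0.08 (adjusted p = 0.0363). The list's median was slightly above 0 and its mean was -0.15, and it did not stand apart (camera adjusted p = 0.137, and adjusted p = 0.54 with an estimated correlation). Of 6 complement genes 0 rose and 2 fell, and 1 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.16, and adjusted p = 0.54 with an estimated correlation). Cfb, of the alternative pathway, fell by 1.46 ± 0.23 (adjusted p = 0.0133), and Serping1, the complement inhibitor, fell by 0.27 ± 0.05 (adjusted p = 0.0416). The call of Fos held without any 1 array. That of Egr1 ended without any array but Ihh 1, Ihh 3 or Shh 3, at up to 0.137, and that of Junb without Ihh 2, Ihh 3, Shh 1, Vehicle 1 or Vehicle 2, at up to 0.161. That of Cfb ended without Vehicle 2, at 0.0816, and that of Serping1 without any array but Vehicle 3, at up to 0.194.

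Of 21 epithelium markers limma called 0 (0 unadjusted, and 0 when adjusted over the list alone), and camera did not set the list apart (adjusted p = 0.722, and adjusted p = 0.915 with an estimated correlation). The level of some of them nevertheless differed between arrays within every group. The epithelial adhesion gene Cdh1 ranged from 4.71 to 8.37 log2 and the keratin Krt8 from 7.54 to 10.62, highest on Shh 3 and Vehicle 1 and lowest on Shh 2 and Vehicle 3, while the epithelial gene Epcam stayed at 7.72 to 7.98. Limma also called 0 of 16 cholesterol synthesis genes, 3 interstitial cell of Cajal markers, 10 mesothelium markers, 6 red blood cell markers and 9 adipocyte markers. At an unadjusted p under 0.05 these held 0, 0, 1 lower, 0, and 1 higher and 1 lower gene. Adjusted over the list alone, only the lipase Lpl among the adipocyte markers passed. The camera adjusted p of the 5 lists was 0.757, 0.747, 0.534, 0.246 and 0.379, and the adjusted p with an estimated correlation 0.915, 0.873, 0.825, 0.465 and 0.541. The median of the mesothelium markers was -0.05 and their mean 0.01, and for the Cajal cell markers these were 0.04 and -0.09, so median and mean differed in sign in both.

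The 274 calls came from limma with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05, 955 genes were higher and 1530 lower, where chance gives 909.65 in all. The count fell to 143 without Ihh 2, 175 without Ihh 3, 156 without Shh 2, 173 without Shh 3, 105 without Vehicle 1 and 99 without Vehicle 2, and was 416 without Vehicle 3. Without Shh 3 and Vehicle 1, the 2 arrays highest in epithelium markers, it was 96, and with the Xist level as a covariate it was 156. Of the 55 named genes called, 26 lost their call without those 2 arrays, among them H2-Aa, Fos and Igf1, and 18 with the Xist covariate. The fit without those arrays kept only treated arrays high in Xist and Vehicle arrays low in it. Its lost calls can therefore not be laid to epithelium.

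Shh alone was compared with Vehicle to ask which genes this ligand changes (3 arrays against 3). Ptch1 rose 2.66-fold (1.41 ± 0.16 log2, adjusted p = 0.00298) and Ltc4s 2.40-fold (1.26 ± 0.08, adjusted p = 9.18e-05). Serpinb2 and Fpr2 were each at least 10.7-fold lower, Arg1 6.84-fold lower, Saa3 5.32-fold lower and Stfa3 at least 4.97-fold lower. Il6 was at least 4.24-fold lower (-2.08 ± 0.22, adjusted p = 0.00199). Limma called 314 genes, of which 89 rose and 225 fell, with 5 rises and 41 falls of at least 2-fold.

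Of the 20 hedgehog target genes 2 rose and 0 fell with Shh, and 7 rose and 0 fell when adjusted over the list alone (camera adjusted p = 0.00243, and adjusted p = 0.146 with an estimated correlation). Hhip rose by at least 0.58 ± 0.12 log2 (adjusted p = 0.0402), while Gli1 differed by 0.79 ± 0.21 (adjusted p = 0.0871), Foxf1 by 0.18 (adjusted p = 0.148) and Bmp4 by 0.27 (adjusted p = 0.235). Of the smooth muscle genes 2 rose and 0 fell, and 4 rose and 1 fell when adjusted over the list alone. They were Synpo2 at 0.91 and Itga8 at 0.53 (adjusted p = 0.0141 and 0.0447), and Myocd differed by 1.06 ± 0.23 (adjusted p = 0.0561). That list passed camera at 0.0011 and lost the call at an adjusted p = 0.444 with an estimated correlation. Of the 35 inflammatory genes 0 rose and 11 fell, and 1 rose and 16 fell when adjusted over the list alone (camera adjusted p = 5.7e-08), a call lost at an adjusted p = 0.0523 with an estimated correlation. The changes of Ccl2 and Cxcl1 were -0.99 and -1.53 (adjusted p = 0.0234 and 0.00217), and Cxcl10 differed by -0.46 (adjusted p = 0.122). Of 16 endothelium markers 0 rose and 2 fell, and 0 rose and 10 fell when adjusted over the list alone. They were the VEGF receptor Flt1 at -0.79 and the adhesion gene Cdh5 at -0.59 (adjusted p = 0.0244 and 0.0464), and the list passed camera at 1.46e-07 but not with an estimated correlation (adjusted p = 0.288). The calls of Hhip, Cdh5 and Flt1 each ended without Ihh 2, Shh 1, Shh 2, Shh 3, Vehicle 1 or Vehicle 2, at up to 0.147, 0.161 and 0.097, that of Ccl2 without Shh 2, Shh 3 or Vehicle 2, at up to 0.0788, that of Synpo2 without Shh 1, Shh 2, Vehicle 1 or Vehicle 2, at up to 0.0575, and that of Itga8 without any array but Ihh 3, at up to 0.169.

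With Shh, 14 of the 26 lists passed camera with the preset correlation and 0 with an estimated one, by which the lowest adjusted p was that of the inflammatory list. At an unadjusted p under 0.05, 1466 genes were higher and 1954 lower. The count of 314 fell to 164 without Ihh 2, 157 without Shh 1, 124 without Shh 2, 137 without Shh 3, 80 without Vehicle 1 and 89 without Vehicle 2, and was 675 without Vehicle 3.

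Ihh alone was compared with Vehicle in the same way (3 arrays against 3). Ptch1 rose 2.91-fold (1.54 ± 0.16 log2, adjusted p = 0.00144), Ltc4s 2.50-fold and Myocd 2.49-fold (1.32 ± 0.23, adjusted p = 0.041), followed by Hsd11b1 at 2.37-fold and H2-Aa at 2.28-fold. Marco was 17.0-fold lower (-4.09 ± 0.18), Fpr2 at least 14.5-fold lower, Serpinb2 at least 11.8-fold lower, Acod1 at least 7.68-fold lower and Cxcl3 6.99-fold lower. Il6 was at least 2.62-fold lower (-1.39 ± 0.22, adjusted p = 0.0218). Limma called 118 genes, of which 35 rose and 83 fell, with 6 rises and 34 falls of at least 2-fold.

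Of the 20 hedgehog target genes 1 rose and 0 fell with Ihh, and 6 rose and 0 fell when adjusted over the list alone (camera adjusted p = 3.42e-06, and adjusted p = 0.0202 with an estimated correlation). Gli1 differed by 0.98 ± 0.21 log2 (adjusted p = 0.0827), Hhip by 0.58 ± 0.12 (adjusted p = 0.069) and Foxf1 by 0.26 (adjusted p = 0.116), none past the threshold. Of the smooth muscle genes 2 rose and 0 fell, and 3 rose and 0 fell when adjusted over the list alone, Myocd and Synpo2 (0.83, adjusted p = 0.0309). That list passed camera at 0.000243 and lost the call at an adjusted p = 0.534 with an estimated correlation. Of the 35 inflammatory genes 0 rose and 11 fell, and 0 rose and 16 fell when adjusted over the list alone (camera adjusted p = 1.38e-17, and adjusted p = 0.00511 with an estimated correlation). The changes of Ccl2, Cxcl1 and Cxcl10 were -1.22, -1.46 and -0.95 (adjusted p = 0.011, 0.00299 and 0.0141). Of 19 NF-kB targets 0 rose and 4 fell, and 0 rose and 12 fell when adjusted over the list alone (camera adjusted p = 5.34e-16, and adjusted p = 0.0334 with an estimated correlation), with Tlr2 at -1.39 and Sod2 at -1.06. Of 19 interferon-stimulated genes limma called 0 (0 higher and 16 lower at an unadjusted p under 0.05), with 16 falls when adjusted over the list alone, and camera lost its call of 1.73e-15 at an adjusted p = 0.391 with an estimated correlation. The call of Myocd ended without Ihh 2, Ihh 3, Shh 1 or any Vehicle array, at up to 0.147, and that of Synpo2 without any array but Shh 1 or Shh 3, at up to 0.0981. The call of Il6 ended without Ihh 2, Vehicle 1 or Vehicle 2, at up to 0.086, that of Cxcl10 without Ihh 1, Ihh 3, Vehicle 1 or Vehicle 2, at up to 0.0853, that of H2-Aa without Ihh 1, Ihh 2 or Vehicle 1, at up to 0.088, that of Hsd11b1 without Ihh 2, at 0.0508, and that of Ccl2 without Ihh 1, at 0.0546.

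With Ihh, 9 of the 26 lists passed camera with the preset correlation and 3 with an estimated one, the hedgehog targets, the inflammatory genes and the NF-kB targets. At an unadjusted p under 0.05, 648 genes were higher and 1024 lower. The count of 118 fell to 68 without Ihh 1, 53 without Ihh 2, 64 without Ihh 3, 65 without Vehicle 1 and 60 without Vehicle 2, and was 229 without Vehicle 3.

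The responses to the ligands were set side by side. Of 339 genes called with either ligand, 334 differed from Vehicle in the same direction with both. Shared rises numbered 27 and shared falls 66, where independent lists would share 0.171 and 1.03, and 0 genes were called in opposite directions. Across genes, which are not independent replicates, the changes correlated with Pearson's r = 0.722. Both comparisons used the same 3 Vehicle arrays. In simulations of unchanged groups, with simulated Vehicle arrays shared in the same way, r was 0.499 (0.434 to 0.566). Their genes were drawn independently, so that range is too narrow for correlated genes. The SE of r from leaving out single arrays (jackknife) was 0.176, and r was 0.571 without Ihh 3. The excess of r over the simulations was therefore not settled. The covariance was 0.0258 against 0.00652 simulated, a difference of 0.0193. The 3 Vehicle arrays were too few to give each comparison controls of its own, so part of the excess over independent lists may come from the shared controls.

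**Figure D3:**
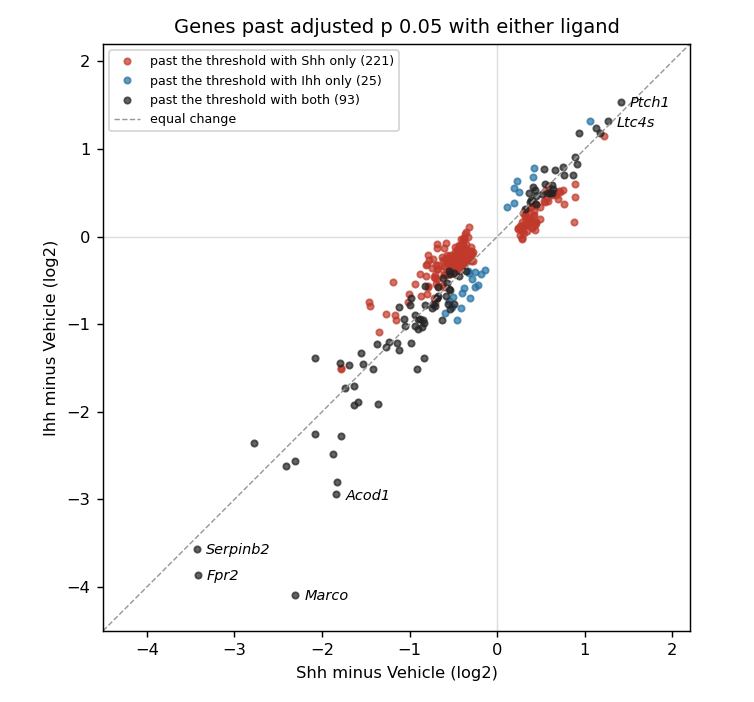
Log2 change with Shh (horizontal) and with Ihh (vertical), each against Vehicle, for the 339 genes called with either ligand, coloured by whether Shh only (221), Ihh only (25) or both (93) passed the threshold. Of these genes 334 lie on the same side of 0 on both axes.

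Shh was tested directly against Ihh (3 arrays against 3), which asks whether the ligands differ in effect. Marco stood at 11.21 ± 0.10 log2 with Vehicle, 8.91 ± 0.07 with Shh and 7.12 ± 0.44 with Ihh (SD, n = 3 each). It was 3.44-fold higher with Shh than with Ihh (1.78 ± 0.18 log2, SE, 95% interval 1.39 to 2.18, adjusted p = 0.0142). Acod1 stood at 8.22 ± 0.02, 6.39 ± 0.15 and 5.28 ± 0.15, and was at least 2.15-fold higher with Shh (1.11 ± 0.09, interval 0.90 to 1.31, adjusted p = 0.00519). These were the only 2 genes that limma called, and 0 were lower with Shh, while at an unadjusted p under 0.05 the counts were 1304 higher and 1086 lower. Ptch1 differed by -0.13 (interval -0.48 to 0.22, adjusted p = 0.725), Gli1 by -0.19 (interval -0.65 to 0.27, adjusted p = 0.694) and Myocd by -0.26 (interval -0.78 to 0.26, adjusted p = 0.628). Il6 differed by -0.69 (interval -1.18 to -0.21, adjusted p = 0.308) and Cxcl10 by 0.49 (interval 0.18 to 0.80, adjusted p = 0.292), neither past the threshold.

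Of the 26 lists, 5 passed camera between the ligands and 0 with an estimated correlation, and limma called 0 of their members. Cell cycle genes lay higher with Shh (adjusted p = 0.0221, and adjusted p = 0.729 with an estimated correlation), a call that ended without Ihh 1 or Shh 1, at up to 0.904. Enteric neuron and glia markers (5.03e-05), endothelium markers (0.00128), hypoxia and glycolysis genes (0.00297) and stress and immediate early genes (0.0222) lay lower, each with an adjusted p = 0.661 with an estimated correlation. At an unadjusted p under 0.05 these 5 lists held 1 higher, 10 lower, 4 lower, 5 lower and 3 lower genes, and adjusted over the list alone 0, 0, 1, 0 and 2, all of them lower. With only the 6 arrays of the ligands in the fit, limma called 0 genes (1223 higher and 1158 lower unadjusted), and Marco lay at an adjusted p = 0.164 and Acod1 at 0.0948. Acod1 held without any 1 array (adjusted p up to 0.0354), and Marco lost its call without Ihh 1, Shh 1, Shh 2, Shh 3, Vehicle 1 or Vehicle 2, at an adjusted p of up to 0.157.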

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

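The tests of fewer immune cells, of a spread between Vehicle arrays and of a weaker response to Shh in all genes were chosen after the result was seen. The test of fewer immune cells replaced an earlier one that had argued against this explanation by comparing the 19 markers with the 13 called inflammatory genes alone, which were picked for their fall.

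Marco and Acod1 differed between the ligands in the direct test, by 1.78 and 1.11 log2, both lower with Ihh. A weaker response to Shh in all genes would give the other genes the same ratio. Over the 66 genes that fell with both ligands the median ratio of the Shh to the Ihh change was 0.944 (0.915 to 0.988), against 0.564 for Marco and 0.624 for Acod1. The range in brackets is a 95% interval from resampling genes, which are not independent replicates, and gives no spread between arrays. Of the 66, 41 changed less with Shh, and 4, with Marco and Acod1 among them, had a ratio no higher than that of Acod1. All 66 had to pass with both ligands against the same Vehicle arrays, which draws ratios towards 1. The median therefore cannot decide on a weaker response to Shh. With the epithelium marker mean as a covariate, a share of at least 0.986 of the difference was left in both genes. That mean spanned much the same range in each group (-0.51 to 0.51 log2 with Ihh, -0.81 to 0.83 with Shh, -0.72 to 0.68 with Vehicle). As a covariate it could therefore hardly move a difference between groups, and the share does not decide on epithelial carry-over. The ranges show only that the markers had no order by treatment. The real split of the 6 arrays gave 0 genes and the highest other 7, all 10 splits gave at least as many as the real one, and 10 splits are too few for a share under 0.05. A stronger effect of Ihh on these genes, or a difference in the dose of the ligands, may account for the pattern, and neither was tested.

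The fall of inflammatory genes had a median of -0.31 log2 over the 35 measured members and -1.37 over the 13 called ones. With the epithelium marker mean as a covariate the median over those 13 was -1.39, and 13 of 13 passed the threshold. This covariate, spread alike over the groups, could hardly move the fall, so it does not decide on epithelial carry-over. Without the 2 arrays highest in epithelium markers Cxcl10, 1 of the 13, lost its limma call (-0.58, adjusted p = 0.182). The other inflammatory genes of this list named for the main comparison kept theirs. That fit dropped Shh 3 (Xist at 6.43 log2) and Vehicle 1 (10.83). All treated arrays left were high in Xist and Vehicle 2 and Vehicle 3 low, so treatment and sex could not be told apart. Without Vehicle 1 alone the count of called genes was already 105, against 96 without both. Lost and kept calls in that fit therefore do not decide on epithelial carry-over. Fewer immune cells in the treated wells stay open. The median of the 19 immune cell markers was -0.15, with a 95% interval of -0.29 to 0.11. That interval came from resampling the markers, which are not independent replicates, and gives no spread between arrays. For 9 of them the 95% interval of the marker's own change lay above the median of all 35 inflammatory genes. Of the markers 1 rose and 6 fell, and Csf1r lay at 12.00 to 12.35 log2 on the 9 arrays. RNA quality, by the Gapdh probe sets given with the data, and a lower inflammatory state of the cells were not tested as explanations.

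The fall of interferon-stimulated genes may reflect a spread between Vehicle arrays rather than the ligands. The lowest Vehicle array lay below the highest treated array by a difference of -0.13 log2 in the list mean (-0.82 on Vehicle 3 and -0.69 on Ihh 2), and 4 of 19 members were lower in all 6 treated arrays than on Vehicle 3. With the epithelium marker mean as a covariate the median was -1.14, against -1.11 without it. Spread alike over the groups, this covariate could hardly move the median, so it does not decide on epithelial carry-over. An effect of the ligands stays open beside the spread between Vehicle arrays.

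Among probe sets without a single gene symbol, which the 4 comparisons by gene did not use, 45 of 10092 passed the threshold for both ligands against Vehicle, 18 higher and 27 lower.

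Other splits of the arrays were counted with a model of the arrays compared. For both ligands against Vehicle, 1 of 84 splits gave as many genes as the real one (217, against 4 for the highest other), a share under 0.05. That makes a chance division of the arrays unlikely but does not exclude it. Other splits mix treated and Vehicle arrays, which widens the spread within groups and lowers their counts. The splits also cannot separate the ligands from other traits unevenly spread over the groups, such as the sex of the embryos by the Xist level. For Shh against Vehicle the real split gave 222 and the highest other 1, and for Ihh against Vehicle 87 and 0, with 1 of 10 splits as large in each, and 10 splits are too few for a share under 0.05.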

How the results depend on the processing

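The 4 alternatives with a covariate or without the 2 arrays highest in epithelium markers were chosen after the data were seen. Counts stayed within 1.5 times with another quantile normalization, centred arrays, a filter on dim genes, the mean of probe sets, every probe set singly, without less specific probe sets and with a trended robust variance. The agreement of the ligands was 0.571 to 0.803 without single arrays, lowest without Ihh 3. It was 0.748 with a filter on dim genes and 0.656 to 0.765 with 3 added alternatives. Its jackknife SE of 0.176 was computed from the fits without single arrays. That each of these fits moved by less than this SE could thus hardly come out otherwise and does not show stability. Centred arrays and the residual component cannot move the agreement. Of 55 called named genes in the main comparison 31 kept their call without any 1 array, 26 lost it without the 2 epithelial arrays and 18 with the Xist covariate. The estimated correlation ended the call of 36 lists over the 4 comparisons. Fry asks another question, whether a list changed at all rather than against other genes. It did not call 22 of the lists that camera called, and called 4 that camera did not. Values near background are compressed by RMA, which limits small changes of dim genes. The log2 of value plus 16 was not run, since the values were log2 already. The labels give no source for a pairing by replicate number. Of the 9 pairs of arrays with the same number, 4 deviated together with r over 0.1 across genes, among them all 3 of Ihh with Vehicle (0.353, 0.226 and 0.543), and 6 of 9 arrays correlated best with their own number, a hint from the data and not the design. With the replicate block the counts were 379 for both ligands, 522 for Shh, 122 for Ihh and 2 between the ligands.

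For both ligands (274 genes) the count was 1126 with array weights, 463 with the epithelium covariate, 713 with the first residual component, 156 with the Xist covariate, 96 without the 2 epithelial arrays, 120 at 1.5-fold, 92 at 0.01 and 99 to 416 without single arrays. For Shh (314) these were 1017, 493, 996, 198, 55, 130, 64 and 80 to 675. For Ihh (118) the count was 498 with array weights, 288 with the residual component, 71 with Xist, 61 without the 2 arrays, 48 at 0.01 and 53 to 229 without single arrays. Between the ligands (2) limma called 0 with only the arrays compared (1223 higher and 1158 lower unadjusted), 7 with the residual component, 1 with Xist, 4 without the 2 arrays, 1 at 0.01 and 1 to 2 without single arrays. Higher fold and stricter thresholds lower a count by construction. The first residual component was taken from the spread within groups of these same arrays. As a covariate it leaves the changes as they are and removes spread, so its higher counts follow nearly by construction. Fits without arrays also have fewer arrays, which by itself can end calls. Beyond these points the cause was not tested.

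The median of the epithelium markers with Shh reversed to -0.43 without Shh 3 (to 0.32 without Vehicle 1), and the cell cycle median between the ligands was 0.0116 without Ihh 1 (its call lost) and up to 0.19 without Ihh 3; the cause was not tested.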

Other observations

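The lists of resident macrophage and MHC class II genes were written after the called genes were seen but before the lists' own values, and no other tests in this part were chosen after the result was seen. H2-Aa rose while Cd14 fell, so a shift of macrophages towards an antigen-presenting state may be part of the response. MHC class II genes lay above other genes for both ligands against Vehicle (7 measured, 6 above 0, median 0.13, camera adjusted p = 0.000784), a call lost at an adjusted p = 0.0548 with an estimated correlation. Limma called 0 of them (3 higher and 0 lower at an unadjusted p under 0.05), with H2-Ab1 at 0.45 (adjusted p = 0.0725), Cd74 at 0.49 (adjusted p = 0.114) and H2-DMa at 0.44 (adjusted p = 0.0874). A resident state stays open without support: outside its list Cx3cr1 rose but Adgre1 fell, and resident macrophage genes did not stand apart (18 measured, 11 above 0, median 0.01, camera adjusted p = 0.358, and adjusted p = 0.39 with an estimated correlation), and limma called 0 (3 higher and 3 lower unadjusted). Of that list, 1 gene, Lyve1, also stands on the endothelium list.

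Transcripts of the X inactivation gene Xist were unevenly spread over the groups, at 10.04 to 11.31 log2 on all treated arrays but Shh 3 (6.43), at 10.83 on Vehicle 1, and at 6.34 and 6.48 on Vehicle 2 and Vehicle 3. The Y-linked Eif2s3y lay at 3.24 on Shh 1 and 3.17 on Shh 2, against 8.44 on Shh 3, 8.66 on Vehicle 2 and 8.98 on Vehicle 3. On Ihh 1, Ihh 2 and Ihh 3 it lay at 8.51, 7.54 and 7.74, and on Vehicle 1 at 6.24, beside high Xist. By these transcripts Shh 1 and Shh 2 came from female embryos and Shh 3, Vehicle 2 and Vehicle 3 from male embryos. The other arrays held both, so the sex of the embryos was unevenly spread over the treatments. The first component of the residuals held 37.6% of the variance within groups.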
